A study of Mus musculus with 8 samples.

How the data were processed

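Hematopoietic stem and progenitor cells were sorted from mouse bone marrow, 2000 cells per sample, and their RNA was sequenced after amplification. Per the labels, 4 samples came from Hdc-/- mice on a C57BL/6 background and 4 from C57BL/6 wild-type (WT) mice. Hdc encodes histidine decarboxylase, the enzyme that makes histamine. Per the labels' protocols, total RNA was extracted with the PicoPure kit, cDNA was amplified with a SMARTer low-input kit, and libraries were made with Nextera XT, a transposon-based kit that does not mark strand. The markers used in the sort, the sex and age of the mice and the deleted part of Hdc are not given in the sources used here.

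The deposited values are raw read counts per gene symbol for all 8 libraries. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2, TopHat2 2.0.4 and HTSeq 0.6.1 were used with genome build mm9. The gene annotation, the strand setting and the counting mode are not given in the sources used here. Reads of overlapping genes and of near-identical copies can therefore be split or lost, which leaves the values of such genes uncertain. The counts carry no molecular identifiers, so amplified copies of a molecule are counted as reads, and counting error alone understates the uncertainty.

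The table holds 23284 entries. Of these, 2 are labelled only with a number. They were left out of library sizes and tests, and their share of the reads was at most 0.0320% in any library. The count columns numbered 1, 2 and 3 for the group labelled Hdc-/- and 1 to 4 for WT were matched to the sample titles by name. The remaining column of the group labelled Hdc-/- carries another number in its name, so it was used as a member of its group without a number, and is called the unnumbered library. Columns left unused numbered 0. Codes in the column names run on within each group, and their meaning is not given. If they mark the order of sorting or library preparation, a batch difference and the group difference cannot be separated.

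Total counts ran from 16327004 to 19780135 reads per library. Libraries of a group were compared before use: Pearson's r across genes, which are not independent replicates, was 0.974 to 0.983 within groups, and the chi-square statistic per gene with at least 80 reads was at least 6.46, well above sampling noise, so no library was a copy of another. The labels do not say that the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

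Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test (glmQLFit with robust dispersion, glmQLFTest), two-sided, with TMM scaling and no covariate. The filterByExpr filter (minimum count 10, minimum total 15) kept 13005 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Every fold change is the libraries labelled Hdc-/- over WT on the log2 scale, its standard error (SE) is the fold change divided by the square root of the F statistic, and levels are in CPM after TMM scaling, as mean ± SD with n = 4.

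Before the data were examined, 22 gene lists for programmes of these cells and 7 lists of markers of other cell types or of sex were fixed, together with the rule for genes named in the text. Sex-linked genes served as a check of balance and had no list test, which left 28 lists. Each was tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01 and adjusted over the 28 lists. Beside it stand camera with a correlation estimated per list, and fry, which asks whether the genes of a list move one way on balance. Named genes are Hdc, the 10 genes with the smallest p in each direction whose groups do not overlap, up to 6 members with the smallest p of each list past the threshold, and up to 4 tested members per list as examples. Some genes that the rule names are not reported here and were left out of the counts over named genes. Genes named outside the rule are marked as chosen after their values were seen. A further list of 30 late erythroid genes was written after many of its members had been seen to rise, and is used only in the closing section.

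Gene names, chromosomes and gene order came from the RefSeq annotation of GRCm38.p6, which matched 12903 of the tested genes (99.2%). It differs from the build of the counts, so no coordinates are given. Order around Hdc is counted in tested genes along chromosome 2. The span of 100 tested genes to each side was chosen after the fold changes were seen, so crowding of calls was tested over 6 spans, from 25 to 300 tested genes to each side, with the strongest taken in the data and in each random placing. The share of genes called there has an exact (Clopper-Pearson) 95% interval.

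The scripts were tested on simulated data with the means, library sizes, edgeR dispersions and 13005 genes of this comparison and 200 changed genes. The edgeR test recovered 70.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 93.9% of those changed 4-fold, and 9 of its 172 calls were false. Camera called the planted list and 0 of 27 unchanged lists, but the simulated genes varied independently of each other. Genes of some real lists varied together, with an estimated correlation of 0.695 for the neutrophil markers. False calls of such lists were not tested.

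Alternatives fixed beforehand were DESeq2 size factors in edgeR, no scaling beyond library size, no filter on low counts, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom without and with sample quality weights, non-robust dispersion, a surrogate variable from sva 3.50.0, the sample number as a block, each library left out in turn, and for lists an estimated correlation and fry. The fit of the 6 numbered libraries without a block and the removal of genes around Hdc were added after the data were seen.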

Results

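RNA from sorted bone marrow hematopoietic stem and progenitor cells was sequenced in 4 samples labelled Hdc-/- and 4 samples labelled WT. The comparison asks how these cells differ in expression in mice that, per the labels, lack the histamine-making enzyme. Libraries held 17223109 to 19780135 reads in the group labelled Hdc-/- and 16327004 to 18059509 in WT, with reads on 14930 to 15209 genes each. On the first principal component, which held 33.97% of the variance, the 4 libraries labelled Hdc-/- lay on one side and the 4 WT libraries on the other. The second, with 14.7%, set WT 1 apart from the other WT libraries.

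Hdc itself went against the labels. Its reads numbered 875, 773, 821 and 740 in libraries 1, 2, 3 and the unnumbered one of those labelled Hdc-/-, against 275, 199, 261 and 263 in WT libraries 1 to 4. Mean levels were 43.0 ± 0.896 CPM in the libraries labelled Hdc-/- and 14.3 ± 1.56 CPM in WT (SD, n = 4), a log2 fold change of 1.58 (SE 0.11, adjusted p = 6.4e-08 by edgeR's quasi-likelihood test). Counts are per gene and the deleted part of Hdc is not given in the labels, so a transcript left by the altered allele would be counted too. The group is therefore called the libraries labelled Hdc-/- throughout, and every direction below rests on those labels.

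In the libraries labelled Hdc-/-, red cell genes were higher, and interferon-response, neutrophil and B cell genes were lower. Of 13005 genes tested, 267 rose and 352 fell. An unadjusted p under 0.05 was found in 2434 of the 13005, the share against which such counts in the lists below are to be read. At least a doubling was seen in 61 of the 267 that rose, and a fall by at least the same factor in 130 of the 352 that fell. The groups did not overlap in 1629 genes (12.5%, against 2.86% by chance). Without Hdc and the genes within 100 tested genes of it on chromosome 2, the counts were 245 higher and 332 lower. The count of higher genes depended on single libraries: it was 175, 137 and 154 without library 2, library 3 or the unnumbered library labelled Hdc-/-, and 170 without WT 2. Without WT 1 it was 382.

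Among the 10 genes with the smallest p that were higher were genes known from red cells: Alas2 and Fech, enzymes at the start and end of heme synthesis, and Bpgm, which makes the hemoglobin regulator bisphosphoglycerate. Tmem87a had the smallest p and rose from 6.31 ± 0.671 to 92.0 ± 5.64 CPM (SD, n = 4, log2 fold change 3.87, SE 0.11, adjusted p = 6.9e-13). Gimap1, a GTPase of lymphocytes, rose by 1.87 (SE 0.07), Wdfy1 by 1.61 (SE 0.10), Fam46c by 4.41 (SE 0.32) and Gatm, an enzyme of creatine synthesis, by 0.93 (SE 0.07). The lower set held Gimap3 (-2.55, SE 0.14), the basophil protease Prss34, the calpain Capn11 (-6.28, SE 0.41, 1 to 3 reads per library labelled Hdc-/- against 82 to 132 in WT), the stem cell antigen Ly6a and the interferon-inducible genes Rtp4 (-1.02), Iigp1 (-1.08) and Gm4951 (-1.68). Tmem87a, Gatm, Slc28a2 (-1.54), Jmjd7 (-3.25) and Kcnip3 (-4.79) lie within 100 tested genes of Hdc. Jmjd7 overlaps Pla2g4b, and Slc28a2 has a close copy nearby, so the values of these genes are uncertain.

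**Figure D1:**
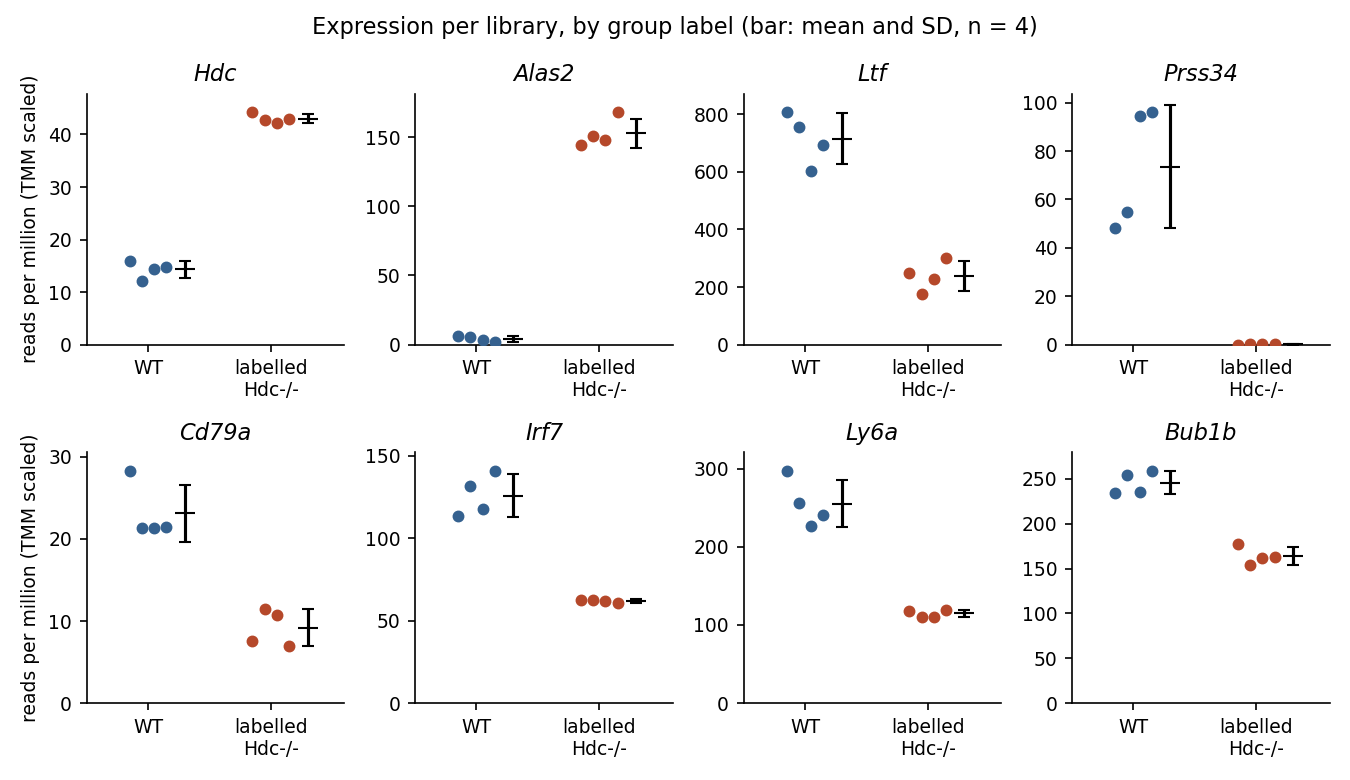
Each panel plots 1 gene, with TMM-scaled CPM on a linear axis from 0. Points are libraries, blue for WT and red for those labelled Hdc-/-, and the bars give the mean and SD of each group (n = 4). Hdc averages 43.0 CPM in the libraries labelled Hdc-/- against 14.3 in WT, Alas2 153 against 4.15, and the groups do not overlap in any panel.

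Red cell genes had the highest median of all the fixed lists. All 4 tested red cell markers rose in the libraries labelled Hdc-/- (median log2 fold change 5.07, camera adjusted p = 2.3e-12, and 0.0158 with an estimated correlation), and 4 rose adjusted over the list alone. Alas2 went from 4.15 ± 2.10 to 153 ± 10.5 CPM, and Slc4a1, the anion exchanger of the red cell membrane, from 0.586 ± 0.727 to 51.5 ± 12.9 CPM (SD, n = 4). Of 12 tested genes of the erythroid list, 7 rose and none fell, and adjusted over the list alone the count was also 7 (camera adjusted p = 3.4e-11, and 0.0376 with an estimated correlation). This list overlaps the first, for example in Alas2 and Slc4a1. Its other members named here rose less: Aqp1, a water channel, by 1.31 (SE 0.24), Klf1, a transcription factor of the lineage, by 1.22 (SE 0.25), and Car2, a carbonic anhydrase, by 0.32 (SE 0.05).

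The entries Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 held at most 1 read in any library. These genes have near-identical copies, so the low counts say nothing of globin RNA. Another globin entry, Beta-s, chosen after its values were seen, rose from 13.0 ± 8.01 to 606 ± 59.0 CPM (SD, n = 4, log2 fold change 5.55, SE 0.41, adjusted p = 0.00037) in the libraries labelled Hdc-/-.

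Neutrophil genes fell as a block. All 10 neutrophil markers were lower in the libraries labelled Hdc-/- (median log2 fold change -1.44, camera adjusted p = 7.4e-24, and 0.0376 with an estimated correlation), and all 10 passed adjusted over the list alone. The granule protein gene Ltf went from 714 ± 88.2 to 237 ± 51.8 CPM (SD, n = 4), and Mmp8 and Mmp9, proteases of neutrophil granules, fell by 1.39 each on the log2 scale. Of 19 myeloid progenitor genes, 10 fell and none rose, with 11 lower adjusted over the list alone (camera adjusted p = 1.5e-10, and 0.0286 with an estimated correlation). Among them were Hp (-1.54, SE 0.15), Ms4a3 (-1.59, SE 0.22), Ly6c2 (-1.19, SE 0.16) and Prtn3, a granule protease (-0.48, SE 0.07).

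B cell markers and 2 basophil proteases fell too. Of 8 tested B cell markers 7 fell, with a median log2 fold change of -1.17 (camera adjusted p = 5.0e-13, and 0.0313 with an estimated correlation), and all 8 were lower adjusted over the list alone. Cd79a, part of the B cell receptor, fell by 1.33 (SE 0.17), the transcription factor Ebf1 by 1.16 (SE 0.16), and the surrogate light chain gene Vpreb1 by 1.18 (SE 0.18). In the mast cell and basophil list 2 of 7 tested genes fell, both basophil proteases, and 4 were lower adjusted over the list alone. Prss34 had 833 to 1720 reads in WT libraries and 0 to 6 in those labelled Hdc-/- (log2 fold change -9.03, SE 0.43), and Mcpt8 fell by 2.24 (SE 0.18). The list passed camera (adjusted p = 0.0021) but not with an estimated correlation (adjusted p = 0.0729), and Cpa3, a mast cell protease, did not pass (-0.42, SE 0.13, adjusted p = 0.084).

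Markers of other cell types had few calls over all genes. Of 4 tested T and NK cell markers, Nkg7 fell by 0.40 (SE 0.07), and the count was the same adjusted over the list alone. The list did not pass camera (adjusted p = 0.0642), but it passed fry as lower (adjusted p = 0.043). None of 10 macrophage markers passed over all genes in edgeR or in limma-voom without sample quality weights, and 6 had an unadjusted p under 0.05. With weights 3 passed, with a surrogate variable 2 and in DESeq2 3, and 6 were higher adjusted over the list alone. The list passed camera as higher (adjusted p = 0.0034), but not with an estimated correlation (adjusted p = 0.158), and Vcam1 (0.53, SE 0.16) and Cd163 (0.40, SE 0.12) had the smallest p. Cd5l, with a larger fold change (1.04, SE 0.32, adjusted p = 0.080), did not pass. None of 5 tested stromal and endothelial markers passed over all genes in edgeR (1 at an unadjusted p under 0.05, 1 in DESeq2, 1 in limma-voom without and 1 with weights, 1 with a surrogate variable). In this list 1 was higher adjusted over the list alone, and the list did not pass (adjusted p = 0.942). Among them was Cxcl12, at 1.48 (SE 0.45, adjusted p = 0.077).

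Interferon-response genes fell together in the libraries labelled Hdc-/-. Of 21 members 18 fell and none rose, with 20 lower adjusted over the list alone. The median log2 fold change was -0.87 (camera adjusted p = 3.5e-34, and 0.0049 with an estimated correlation). Irf7, the transcription factor that amplifies type I interferon, went from 126 ± 12.8 to 61.9 ± 0.993 CPM (SD, n = 4, log2 fold change -1.02, SE 0.08, adjusted p = 3.2e-07). Oas2, a sensor of double-stranded RNA, fell by 1.09 (SE 0.09), and Usp18, which restrains interferon signalling, by 1.01 (SE 0.07). This fall went along with that of the neutrophil and B cell markers, whose medians were -1.44 and -1.17.

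Genes of mitosis were lower in the libraries labelled Hdc-/- by a small step. Of 22 genes of the G2 and mitosis list 11 fell, none rose, and 19 were lower adjusted over the list alone, with a median log2 fold change of -0.30. This fall went along with the larger ones of the neutrophil and B cell markers (medians -1.44 and -1.17). Bub1b, of the spindle checkpoint, fell by 0.58 (SE 0.06), the mitotic kinases Cdk1 and Aurkb by 0.40 (SE 0.07) and 0.32 (SE 0.07), and Top2a by 0.23 (SE 0.05). The list passed camera (adjusted p = 1.7e-15) but not with an estimated correlation (adjusted p = 0.0729). Of 20 S phase genes only Pcna, the sliding clamp of DNA replication, fell (-0.47, SE 0.08), over all genes and adjusted over the list alone. The S phase list passed camera (adjusted p = 0.0272) but not with an estimated correlation (adjusted p = 0.316) nor without genes around Hdc (adjusted p = 0.0747). Bub1b and Pcna both lie within 100 tested genes of Hdc.

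Genes of stem cell identity moved by small amounts, except for Ly6a. Ly6a encodes Sca-1, a surface protein much used to sort these cells, and fell from 255 ± 30.4 to 115 ± 4.89 CPM in the libraries labelled Hdc-/- (SD, n = 4, log2 fold change -1.15, SE 0.08, adjusted p = 7.6e-08). Of the 20 genes of the list 3 rose, among them Eya1 by 0.34 (SE 0.08) and Hoxa9 by 0.31 (SE 0.07), with 4 higher and 1 lower adjusted over the list alone. The list passed camera as higher (adjusted p = 0.0326) but not with an estimated correlation (adjusted p = 0.118). This small rise went along with the falls of the neutrophil and B cell markers (medians -1.44 and -1.17). Of 18 quiescence genes, Txnip (0.42, SE 0.06) and Tob1 (0.48, SE 0.13) rose, the same number adjusted over the list alone, and the list did not pass (adjusted p = 0.0955). The calls of Eya1 and Hoxa9 each ended in 6 of 19 alternatives and that of Tob1 in 10. Other calls named in this text were lost in 5 to 9 of them: Bbc3 in 9, Itga4, Per1, Satb1 and Xbp1 in 8, Hmox1 and Robo4 in 7, Hspa5, Itgb2, Notch1 and Slc18a2 in 6, and Flt3, Gp9 and Top2a in 5.

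The lymphoid priming list split. Of its 17 genes 5 rose and 2 fell in the libraries labelled Hdc-/-, with 7 higher and 2 lower adjusted over the list alone. Flt3, a cytokine receptor of early progenitors, rose by 0.24 (SE 0.06), Mef2c by 0.31 (SE 0.05) and Notch1 by 0.29 (SE 0.07), while the B cell precursor genes Igll1 (-1.44, SE 0.19) and Blnk (-1.12, SE 0.16) fell beside the B cell markers. The list did not pass camera (adjusted p = 0.0992), but it passed fry as higher (adjusted p = 0.031). Of 13 tested megakaryocyte genes Gp9, a platelet glycoprotein, rose by 0.54 (SE 0.13), 4 were higher adjusted over the list alone, and the list did not pass (adjusted p = 0.115). Among 16 tested genes of niche adhesion and homing, the integrin genes Itgal (0.39, SE 0.07) and Itga4 (0.23, SE 0.06) and the guidance receptor gene Robo4 (0.33, SE 0.08) rose and Itgb2 fell (-0.27, SE 0.06), with the same counts adjusted over the list alone. That list did not pass camera either (adjusted p = 0.247), but it passed fry as higher (adjusted p = 0.031).

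**Figure D2:**
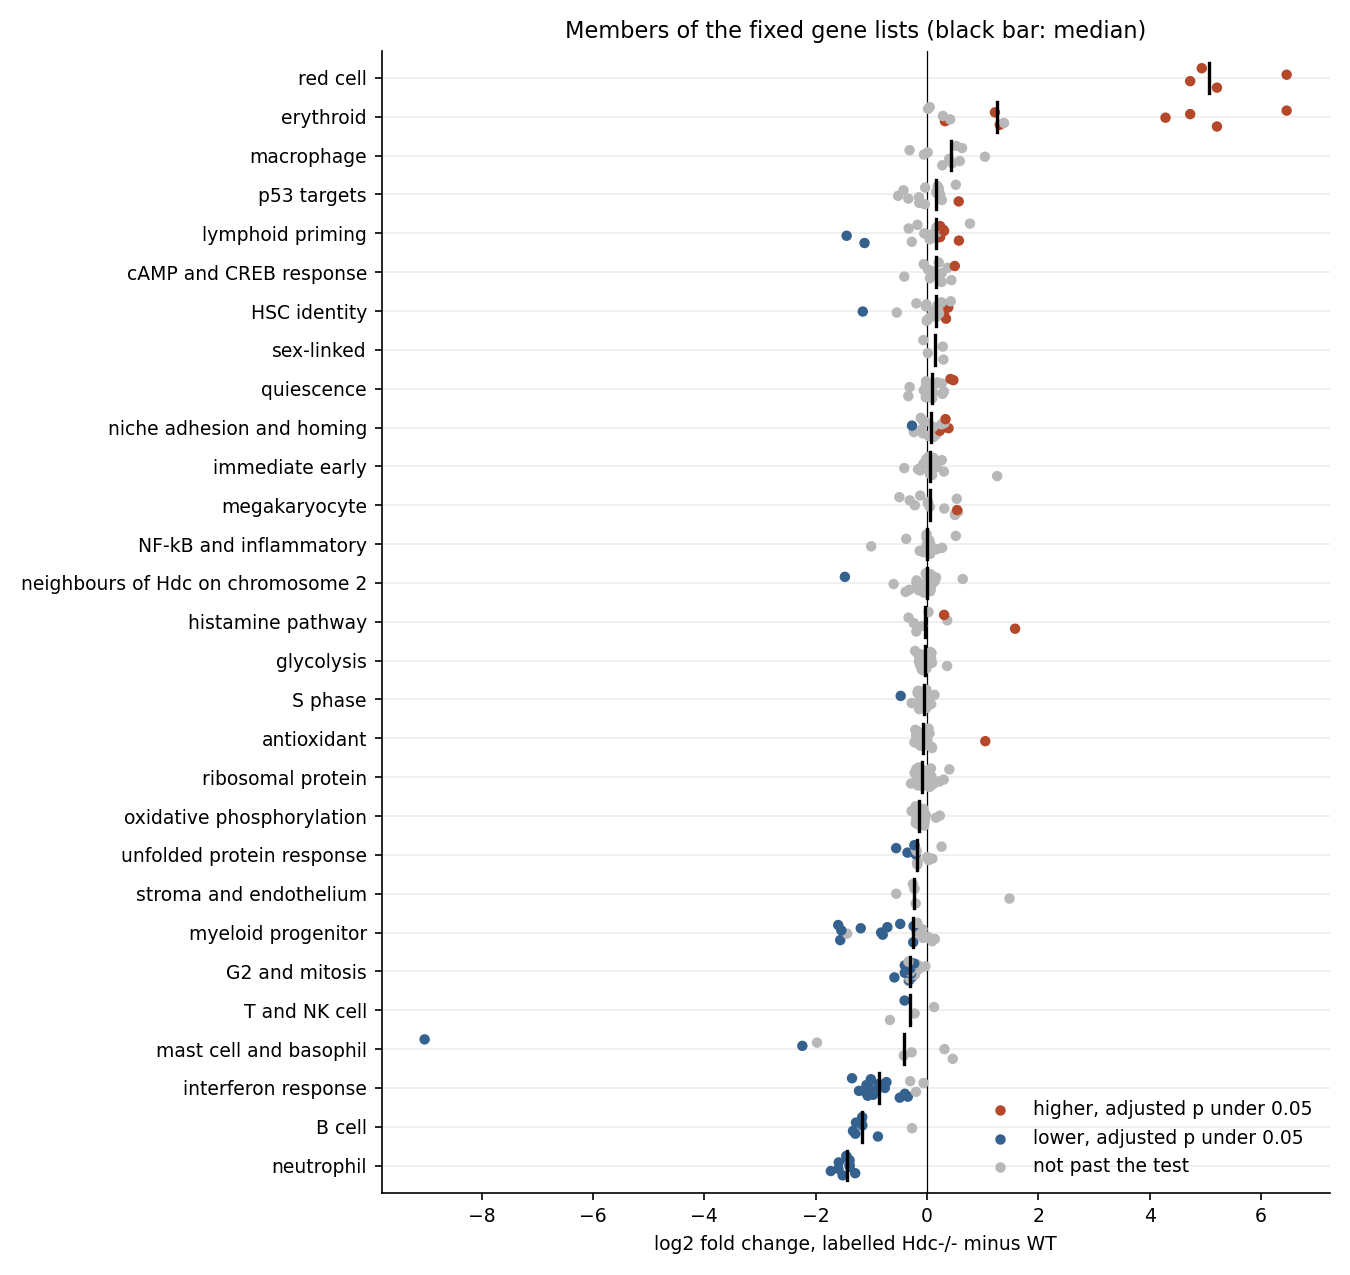
Each point is a tested member of a fixed gene list, placed on the horizontal axis by its log2 fold change, labelled Hdc-/- minus WT. Red and blue points passed the edgeR test as higher and lower, grey points did not, and black bars are list medians. Medians run from -1.44 for neutrophil markers to 5.07 for red cell markers, and most lists lie near 0.

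Beyond Hdc, only Slc18a2 of the histamine pathway passed over all genes, though 5 of the 8 tested members, Hdc among them, had an unadjusted p under 0.05. Of 8 tested members, Hdc and Slc18a2, the vesicular transporter that loads histamine, rose in the libraries labelled Hdc-/-, Slc18a2 by 0.31 (SE 0.08, adjusted p = 0.032), and the counts were the same adjusted over the list alone. The H2 receptor gene Hrh2 did not pass (0.37, SE 0.15, adjusted p = 0.20), nor did the list in camera (adjusted p = 0.21). With fry the list, which holds Hdc itself, passed as higher (adjusted p = 0.00235) and for change in either direction (adjusted p = 6.1e-07). H2 receptors signal through cAMP: of 12 tested genes of the cAMP and CREB response Per1, a clock gene, rose by 0.50 (SE 0.13), and 4 were higher adjusted over the list alone. That list passed camera as higher (adjusted p = 0.0441) but not with an estimated correlation (adjusted p = 0.343).

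Immediate early and inflammatory genes had no call over all genes in edgeR or in limma-voom without sample quality weights. With weights 1 gene of each list passed, and with a surrogate variable 1 of each. Of 18 tested immediate early genes 4 had an unadjusted p under 0.05, 1 passed in DESeq2 and none passed adjusted over the list alone, with Klf6 at 0.27 (SE 0.08, adjusted p = 0.060). Of 14 tested NF-kB and inflammatory genes 4 had an unadjusted p under 0.05, 1 passed in DESeq2 and 1, Icam1 (0.27, SE 0.08), was higher adjusted over the list alone. Neither list passed (adjusted p = 0.278 and 0.911).

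Metabolic and housekeeping lists changed little. None of 30 oxidative phosphorylation genes passed over all genes in edgeR or in limma-voom without sample quality weights, and 12 had an unadjusted p under 0.05. With weights 2 passed, with a surrogate variable 4 and in DESeq2 4, while 1 was higher and 4 were lower adjusted over the list alone. The median was -0.14, and the list passed camera as lower (adjusted p = 8.3e-05) but not with an estimated correlation (adjusted p = 0.422). This small fall went along with the larger ones of the neutrophil and B cell markers (medians -1.44 and -1.17). None of 19 glycolysis genes and none of 41 ribosomal protein genes passed over all genes in edgeR, DESeq2 or limma-voom without sample quality weights, or adjusted over the list alone (5 and 7 at an unadjusted p under 0.05). With weights 1 glycolysis gene passed, and with a surrogate variable 1, against 0 ribosomal protein genes. Neither list passed camera (adjusted p = 0.235 and 0.115). Of 14 tested genes of the unfolded protein response 4 fell and 7 were lower adjusted over the list alone. Sdf2l1 (-0.55, SE 0.08), Manf (-0.35, SE 0.09), Xbp1 (-0.23, SE 0.06) and Hspa5 (-0.20, SE 0.05) are chaperones of the endoplasmic reticulum or, for Xbp1, a regulator of them. That list passed camera as lower (adjusted p = 1.0e-04) but not with an estimated correlation (adjusted p = 0.156), and fell beside 10 of 10 neutrophil markers, 7 of 8 B cell markers and 10 of 19 myeloid progenitor genes. Hmox1, which breaks down heme, rose by 1.05 (SE 0.25) as the only call among 18 antioxidant genes, and Bbc3, which promotes cell death, by 0.57 (SE 0.15) as the only call among 15 p53 targets, with the same counts adjusted over each list alone. Neither list passed (adjusted p = 0.378 and 0.278).

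Of the 28 lists 14 passed camera, and 6 of these held with an estimated correlation: red cell, erythroid, neutrophil, B cell, myeloid progenitor and interferon response. With fry 15 lists passed for a net direction and 20 for change in either direction. Of the lists lost with the estimate, 5 passed fry for a net direction: mast cell and basophil (adjusted p = 0.00266), G2 and mitosis (0.00302), unfolded protein response (0.00745), macrophage (0.0282) and HSC identity (0.031). S phase (fry adjusted p = 0.0526), cAMP and CREB response (0.124) and oxidative phosphorylation (0.181) did not. In the lymphoid priming, histamine pathway, NF-kB and stromal lists the mean and the median of the fold changes differed in sign.

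Calls were frequent in a span around Hdc, mostly to one side of it. In that list, fixed beforehand, 1 of 28 tested genes fell, Slc27a2 (-1.47, SE 0.29), with 3 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.229). That list leaves out the called gene Kcnip3 (order 17 from Hdc). Before Hdc it ends at Sema6d (order -14), short of called genes such as Sqrdl (order -15) and Gatm (order -20). Of all 50 genes within 25 tested genes of Hdc, 10 were called (20%). Over the wider span chosen after the data were seen, 41 of 200 genes within 100 tested genes of Hdc were called (20.5%, 95% interval 15.1 to 26.8), 21 higher and 20 lower in the libraries labelled Hdc-/-. Of these calls 33 lay among the 100 genes before Hdc (15 higher, 18 lower) and 8 among the 100 after it (6 higher, 2 lower), in the order of the chromosome. On the rest of chromosome 2 the share was 37 of 820 (4.51%), and on other chromosomes 536 of 11882 (4.51%). Of 4 Y-linked genes tested for balance none passed in edgeR, limma-voom or DESeq2 over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05), with Ddx3y at 0.30 (SE 0.12, adjusted p = 0.20), and Xist had 1 to 12 reads per library except WT 4, with 41.

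**Figure D3:**
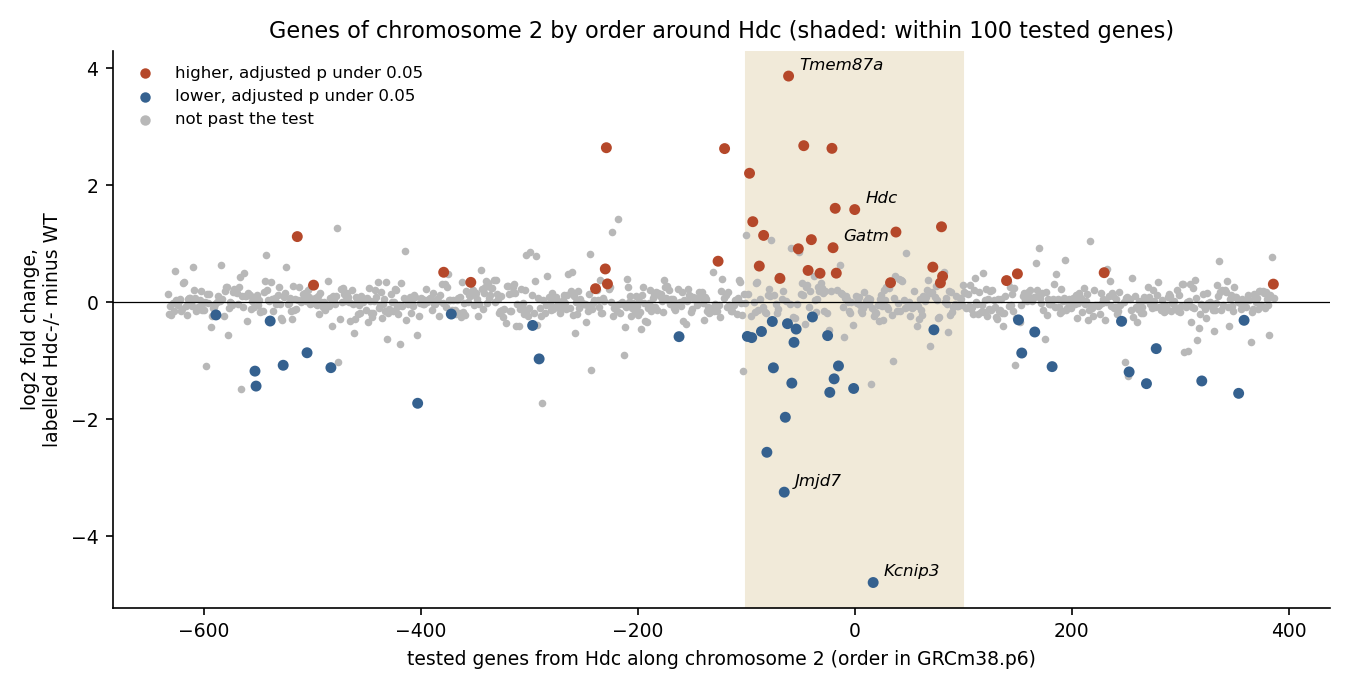
Each point is a tested gene of chromosome 2, placed by its order from Hdc (counted in tested genes) and by its log2 fold change, labelled Hdc-/- minus WT, with red and blue for genes that passed as higher and lower and grey for the rest. In the shaded span of 100 tested genes to each side 41 of 200 genes other than Hdc passed, against 37 of 820 beyond it.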

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

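The tests below of cell markers, scaling, shares of cells, late erythroid genes and gene order were chosen after the results were seen. The test of exchanged labels and the counts over other splits of the libraries were set beforehand.

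Hdc reads were higher in the libraries labelled Hdc-/-, with all 4 above all 4 WT libraries. More basophils or neutrophils, which make Hdc, are argued against by their own markers. With markers of mast cells, which make Hdc too, 13 had at least 5 CPM (Kit, which stem cells express, was left out). For mast cells the test rests on Cpa3 alone (-0.42, SE 0.13), so more mast cells cannot be judged from it. The highest log2 fold change plus 2 SE among the 13, that of Cpa3, was -0.155, below the lower bound of Hdc (1.37). Scaling moves all genes of a library alike and is argued against too, since only 0.469% of the other tested genes had a log2 fold change at or above that lower bound. Whether the group labels were exchanged cannot be told apart from correct labels by the genes around Hdc, whose median log2 fold change differed from that of other genes by -0.00519 (permutation p = 0.743, 159 genes around Hdc with a mean of at least 5 CPM), because those genes went both ways. A transcript that the altered allele still makes, perhaps at a raised level, stays open and was not tested, since counts are per gene.

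Markers of mature blood cells moved in opposite directions between the groups. A lower share of the target cells in either group alone would raise the markers of every other type, but the median of the neutrophil markers was -1.44 while the lowest red cell marker minus 2 SE was 3.67. Fewer neutrophils in the libraries labelled Hdc-/- is a candidate explanation for part of the pattern: all 10 markers, each at 5 CPM or more in WT, fell by about the same factor (SD over markers 0.687 times their median SE), and Ngp, named after its values were seen as the most abundant of them, went from 919 to 306 CPM. The markers vary together between libraries (estimated correlation 0.695), which by itself lowers that ratio. It cannot tell fewer neutrophils from a shared fall of these genes within progenitors. More late erythroid cells cannot be told apart from a change of these genes within progenitors: 18 of 28 tested late erythroid genes (64.3%) were higher and 0 lower, namely 7 of the 13 at 5 CPM or more in WT and 11 of the other 15, and the list was partly drawn from genes already seen to rise. A sort gate that removes mature cells would bear on both, its markers are not given, and a difference in the marrow of the groups stays open as untested.

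Called genes crowded around Hdc on chromosome 2, with 33 of 100 on one side called and 8 of 100 on the other (Fisher's exact p = 1.6e-05, a split seen before it was tested). Chance placing is argued against: none of 10000 random placings of the calls gave as extreme a crowding at the best of 6 spans (permutation p = 1e-04, the smallest these can give). A local effect of the altered allele that fades with distance cannot be told apart from one that does not, since the share called within 25 tested genes was 0.968 times that from 26 to 100 (95% interval 0.51 to 1.83). Close to Hdc calls were rare: only Slc27a2 (order -1) was called nearer to it than Sqrdl (order -15), a limit chosen after the values were seen. A segment of another strain carried along with the altered allele cannot be told apart from a regional effect of the allele: 48.8% of the calls in the span went the rarer way, which both allow, and the span was chosen after the data were seen. Neither was tested against the 245 higher and 332 lower genes elsewhere.

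Over the 35 splits of the 8 libraries into 4 and 4, only the real 1 reached 267 higher genes, and only the real 1 reached 352 lower genes. The highest count of any other split was 0 in either direction, and 1 of 35 is the smallest share these splits can give. The other splits mix the groups, so genes that differ between the groups widen the spread within each part. Few calls are then likely in any case, so these counts do not measure chance and do not exclude it. For the 14 lists past the threshold, 2 of the 35 splits gave as many, and the highest other split gave 16, with library 1 of those labelled Hdc-/- and WT 1, 2 and 4 against the rest. That split keeps most libraries of each group together, and so part of the group difference, so it is no measure of chance. These splits leave chance undecided for the number of lists.

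In 19 of 274 groups of 4 libraries, 1 library lay far from the other 3, against 13.7 expected, since chance flags about 1 in 20. WT 1 was that library 7 times, with 4.76 CPM of Capn11 (others 7.31 to 7.67), 608 of Txnip (551 to 556), 137.8 of Pcna (109 to 111), 6.67 of Hmox1 (16.9 to 18.5), 72.3 of Ccng1 (95.7 to 96.9), 1243 of Rplp0 (1012 to 1047) and 28.3 of Cd79a (21.3 to 21.5). Of the other WT libraries, WT 2 had 158 CPM of Itga4 (173 to 176), WT 3 had 0.111 of Fam46c (1.01 to 1.16) and 22.5 of Cdkn1a (17.7 to 17.97), and WT 4 had 1.51 of Plvap (3.13 to 3.54). Library 1 of those labelled Hdc-/- had 0.152 CPM of Capn11 (0.0513 to 0.0580), 74.5 of Hoxa9 (78.9 to 79.8), 74.6 of Itga2b (67.7 to 68.7) and 5.41 of Tnf (6.67 to 6.95). The unnumbered library had 120.2 CPM of Wdfy1 (114 to 115), 80.8 of Pcna (85.2 to 85.8), 98.3 of Ccng1 (111 to 113) and 30.4 of Mmp9 (22.3 to 23.5).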

How the results depend on the processing

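Hdc stayed higher and past the threshold in every alternative, at 1.515 to 1.64 on the log2 scale. Against 267 higher genes, DESeq2 called 448, limma-voom with sample quality weights 422 and a surrogate variable 456. Leaving out single libraries gave 137 to 382, the most without WT 1, where 815 genes were called in all. The count of higher genes fell by over 1.5 times without library 2 (175), library 3 (137) or the unnumbered library (154) labelled Hdc-/-, or WT 2 (170). Lower genes stayed within 1.5 times of 352 in those settings. DESeq2 called 948 genes in all against 619, 618 of them shared. On simulated data 10.8% of its calls were false, against 5.23% for edgeR. That was a single run built on edgeR's own dispersions and filter, which may favour edgeR. Sample numbers did not pair the libraries: deviations from the group means correlated at -0.0591, -0.0187 and 0.00715 in the 3 numbered pairs. The replicate block on these 6 libraries gave 123 higher and 189 lower genes. The 6 libraries without a block, a fit added after the data were seen, gave 134 and 211, so the drop came mostly with the fewer samples. Leaving out the genes around Hdc, also added later, gave 245, 332 and 13 lists. The number of lists went from 14 to 6 with an estimated correlation, and was 11 to 16 with single libraries left out. Among the lists lost with it, the estimate was 0.68 for oxidative phosphorylation and 0.345 for G2 and mitosis, against the preset 0.01. It was -0.00813 for HSC identity, so whether higher correlation accounts for every loss was not tested. Of 79 named genes past the threshold 56 kept their call in all alternatives that tested them and 17 lost it in at least 5: Tob1 (10 of 19), Bbc3 (9), Itga4, Per1, Satb1 and Xbp1 (8 each), Hmox1 and Robo4 (7 each), Eya1, Hoxa9, Hspa5, Itgb2, Notch1 and Slc18a2 (6 each), and Flt3, Gp9 and Top2a (5 each). No named gene and no list reversed past the threshold. Depth limits genes near the floor, such as Prss34 and Capn11, whose fitted fold changes rest on 0 to 6 reads in the libraries labelled Hdc-/-.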

Other observations

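All families and genes described here were chosen after their values were seen, except Gimap1, Gimap3 and Cd74. The rule fixed beforehand named these for their small p in these data. The counts of calls per family were the same under all 3 scalings, which differ little. Of 9 tested Schlafen genes, a family of immune cells in part induced by interferon, 5 fell and 1 rose in the libraries labelled Hdc-/-: Slfn4 (-2.27, SE 0.19) and Slfn2 (-1.33, SE 0.12) were among those that fell, and the pseudogene Slfn14-ps is the exception (3.83, from 0.175 CPM in WT). Of 9 genes of the MHC class II region the antigen-presenting chains H2-Aa (-1.24), H2-Ab1 (-1.08) and H2-Eb1 (-1.67) fell, beside the fall of the B cell markers and of Cd74, their invariant chain, while H2-Ob rose by 0.36. Of 9 guanylate-binding protein (Gbp) genes, induced by interferon, 5 fell and 0 rose in edgeR's test, and of 6 Ifitm genes 3 fell and 0 rose, among them Ifitm3 (-0.59). The falls in the Schlafen, Gbp and Ifitm families went along with those of the neutrophil and B cell markers (10 of 10 and 7 of 8 lower, medians -1.44 and -1.17).

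The Gimap genes, GTPases of lymphocytes that lie side by side on chromosome 6, split. Gimap1 was higher in the libraries labelled Hdc-/- (266 against 73.0 CPM), while Gimap3 (6.81 against 40.0), Gimap4 (-1.48 on the log2 scale) and Gimap7 (-1.13) were lower, and the other 4 tested members did not pass. Members of this family resemble each other, so reads can be split between them. Rn45s and Lars2, which hold many reads in these libraries, took 0.847% to 1.43% and 0.956% to 1.23% of the reads, with overlapping ranges in the groups.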
